A study of Mus musculus with 3 samples.

How the data were processed

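Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed in 3 mouse libraries. Antiserum against the transcription factor T-bet was used on wild-type Th1 cells and on Th1 cells from T-bet-deficient mice, and the third library was whole-cell extract of wild-type cells that had not been immunoprecipitated. Each group held 1 library, so no difference between groups has a replicate check and no p-value for a difference between groups is given.

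Per the submitters' processing notes, the software was CASAVA and MACS and the genome build was mm9; versions and alignment settings are not given in the sources used here. The deposited read files list 1 aligned read per line, as an interval of 36 bp with a strand and an alignment score. The definition of that score is not given, and it was not used. The labels state reads of 35 bp, whereas the peak files' headers record a tag size of 36 bp. Per the file headers, the authors called peaks in each ChIP library separately against the whole-cell extract with MACS, at a p-value cutoff of 1e-06, a band width of 150 and a model fold of 15. The fragment shift parameter d that MACS estimated was 110 for the wild-type list and 38 for the knockout list, per the file headers. For each peak the deposited lists give a count of ChIP tags, a fold enrichment over the local extract level (a ratio), a false discovery rate in percent and a score equal to 10 times the negative log10 of the p-value. These are the authors' own values per peak and were used only to describe, rank or filter peaks within a list.

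Reads were counted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Of reads that shared a start position and strand, 1 was kept. The kept numbers, 11705892 for the wild-type ChIP, 12955911 for the knockout ChIP and 21789208 for the extract, differed by 0 from the unique tag numbers in the file headers. Each read was moved 100 bp towards the centre of its fragment and counted in the wild-type peaks. Counts were scaled to 1000000 kept reads (RPM). Peaks called in the knockout library are often shorter than that shift, so reads in knockout peaks were counted at their 5' ends. Ratios between libraries carry exact conditional (Clopper-Pearson) 95% intervals and shares carry exact Clopper-Pearson 95% intervals. These cover counting error only, since reads amplified by PCR are not independent molecules. A wild-type peak was said to pass the knockout rule when its RPM ratio over the knockout library was at least 2 and the 95% interval lay above 1. The rule was tested on simulated data, with counts drawn for the same 17173 peaks. It called 1.03% of 16973 unchanged peaks, 28.4% of 67 peaks raised by a fold of 2, 70.1% of 67 at a fold of 4 and 100% of 66 at a fold of 8. The unchanged peaks were drawn at a ratio of 1, so 1.03% is not the share of regions away from peaks in these libraries that pass the rule; that share was measured as 36.7% in windows away from peaks. Those were autosomal windows of 1 kb, drawn to have the mean extract level of windows around 8331 peaks, with the level set on a random 50% of the extract reads. Windows away from peaks were drawn with replacement, so a window can occur more than once. Intervals over such windows may therefore be too narrow.

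Overlap of peaks required at least 1 bp (bedtools 2.31.1). Chance overlap came from 100 random placements of the knockout list within chromosomes. Neighbouring peaks were joined into regions where the gap was at most 12.5 kb, and the same was done for 100 placements of the peaks at positions of extract reads. For the comparison with a library's own surroundings, the sequence within 100 bp of each summit was set against that 2 to 5 kb to either side, in peaks with no other peak within 10 kb, with intervals from 1000 bootstrap resamples of peaks. The rule for the peaks named in the text was fixed before the data were examined, with coordinates in place of genes where genes could not be assigned. It takes the 10 wild-type peaks with the highest deposited fold enrichment among those with at least 50 tags and no knockout peak on them, and the 5 knockout peaks with the highest fold enrichment. All other regions named, the joining of peaks into regions and the comparison of chromosomes were chosen after the data were seen.

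No genome sequence or gene annotation in mm9 was used here. The gene table at hand belongs to GRCm38.p6, a different build, so its coordinates were not used and peaks were not assigned to genes. The planned comparisons of peak location, gene lists, motifs and the Irf4 locus were therefore not analysed here, and regions are given by mm9 coordinates counted from 1. From that table only the number of protein-coding genes per chromosome was taken. Processing alternatives covered the peak threshold, the meaning of a shared peak, repeat reads, the scaling, the read shift, the depth and the choice of control.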

Results

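The data set asked where T-bet binds in the genome of Th1 cells. T-bet, encoded by Tbx21 on chromosome 11, is the transcription factor that directs naive CD4 T cells to the interferon-producing Th1 fate. Sorted naive cells had been activated through CD3 and CD28 with IL-2, IL-12 (20 ng/ml) and an antibody against IL-4. The resulting Th1 cells were restimulated with PMA and ionomycin, which mimic receptor signalling, for 4 hours before crosslinking. The same antiserum was used on cells from T-bet-deficient mice, as a control for what the antiserum and beads recover without their target. Whole-cell extract of wild-type cells served as the input, and there was no extract of the knockout cells. Each of the 3 groups held 1 library.

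The wild-type T-bet ChIP library held 14765810 aligned reads, the knockout ChIP library 18501050 and the extract 22593301. Reads repeating an already occupied position and strand made up 20.7% of the wild-type ChIP reads (95% interval 20.70 to 20.74), 30.0% of the knockout ChIP reads (29.95 to 29.99) and 3.56% of the extract reads (3.551 to 3.567). After their removal 11705892, 12955911 and 21789208 reads remained. A count of 0 in a peak allows up to 3 reads, or 0.256 RPM in the wild-type ChIP, 0.232 RPM in the knockout ChIP and 0.138 RPM in the extract.

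The targeted gene, Tbx21, was not examined, since no mm9 position of it was used here. Instead, the genome was searched for stretches of at least 2 kb that held no knockout read and at least 20 reads in each wild-type library. There were 33 such stretches, of which 4 lay on chromosome 11. None of them was assigned to a gene, and the same search found 239 stretches that lacked wild-type ChIP reads and 0 that lacked extract reads. The search therefore did not test the deletion, and the genotype rests on the labels. With all reads as deposited, 91 stretches lacked knockout reads.

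Far more discrete regions were called with T-bet antiserum in wild-type Th1 cells than in cells without T-bet. The wild-type list held 17173 peaks and the knockout list 746, both called against the same extract. Wild-type peaks had a median length of 552 bp (interquartile range 443 to 701) and covered 10.4 Mb in all. Knockout peaks had a median length of 79 bp (interquartile range 55 to 110) and covered 0.0821 Mb. The false discovery rate reported by the peak caller was at most 3.56% for every wild-type peak. It was 100% for 589 of the 746 knockout peaks (79.0%), and 4 knockout peaks had a rate of at most 5%. Of the knockout peaks, 327 (43.8%) were shorter than 72 bp, the length of a pair of adjoining reads. The caller had used a fragment shift parameter of 38 bp for this library, near the read length, and 110 bp for the wild-type library. The lists were thus not called with the same parameter. How far this changed the numbers and lengths of peaks was not tested, so their contrast cannot be put down to T-bet alone. The number of pairs of reads on opposite strands was greatest at a distance of 150 bp in the knockout library, with a lower maximum at 35 bp, and at 135 bp in the wild-type ChIP. The extract also had a maximum at 35 bp, at 1.24 of the level at the largest distances, above its maximum of 1.18 at 145 bp. Within the called peaks the median offset between strands was 102 bp in the wild-type list and 33.5 bp in the knockout list.

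**Figure D1:**
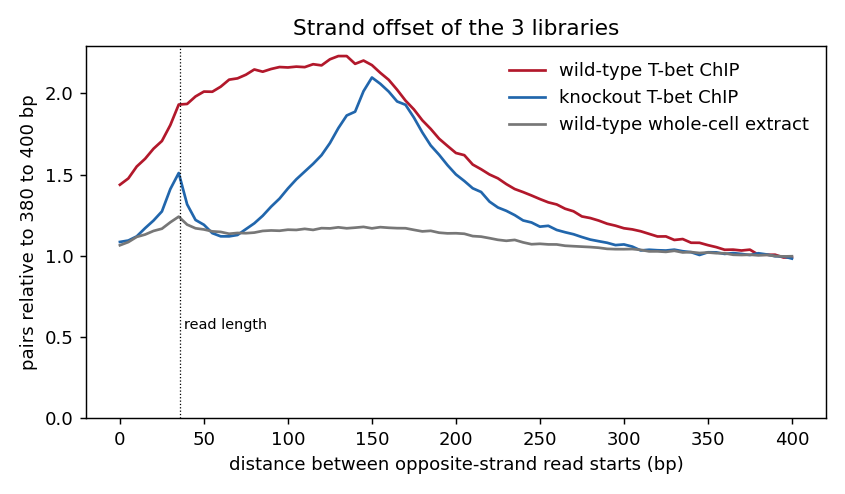
Number of read pairs on opposite strands (y axis, relative to the largest distances) against the distance between their starts in bp (x axis) for the 3 libraries, with 1 read kept per position and strand. The knockout library has maxima at 35 bp and 150 bp, the extract has maxima at 35 bp and 145 bp, and the dotted line marks the read length of 36 bp.

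Very few wild-type regions were also called without T-bet. A total of 96 wild-type peaks (0.559%, 95% interval 0.453 to 0.682) overlapped a knockout peak. Conversely 105 knockout peaks (14.1%, 95% interval 11.7 to 16.8) lay on a wild-type peak. In 100 random placements within chromosomes, a mean of 3.57 and at most 9 wild-type peaks were overlapped. With placement at positions of extract reads the mean was 15.2 and the maximum 24. In 77 of the 96 shared regions RPM was higher in the knockout than in the wild-type ChIP, with medians of 2.74 and 1.75 RPM against 0.229 RPM in the extract. Summed over all 96, the wild-type to knockout ratio was 1.101 (95% interval 1.076 to 1.125), and without the peak with the most reads, on chromosome 17, it was 0.952 (0.923 to 0.982). These sums used kept reads. With all reads as deposited, scaled to library size, the 96 regions together held more knockout than wild-type signal. The direction of the sum therefore depends on the repeat reads. Only 1 of the 96 passed the knockout rule. Using only knockout peaks with a false discovery rate of at most 5% left 3 shared peaks. The knockout peaks were called against the wild-type extract, with a smaller fragment shift parameter than the wild-type peaks. The knockout ChIP stood at a median of 0.420 of that extract over wild-type peaks, and at 0.491 in extract-rich windows away from peaks. A moderate enrichment in the knockout could therefore go uncalled at such sites, and the low overlap does not show that there was none.

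At the wild-type peaks the T-bet signal was above that of both controls. The peaks had been called for an excess over this same extract, so the ratio over the extract restates that selection. The ratio over the knockout uses the same selected wild-type reads, so it is not independent of the selection either. The median peak held 38 reads in the wild-type ChIP, 5 in the knockout ChIP and 18 in the extract, or 3.25, 0.386 and 0.826 RPM. The ratio of wild-type to knockout ChIP had a median of 9.30 over peaks (interquartile range 6.24 to 15.1), and the ratio of wild-type ChIP to extract a median of 4.03 (interquartile range 3.02 to 5.89). In all, 7.04% of wild-type ChIP reads (95% interval 7.03 to 7.06), 0.867% of knockout ChIP reads (0.862 to 0.872) and 1.83% of extract reads (1.82 to 1.83) fell in these peaks. Among peaks with no other peak within 10 kb, read density at the summit was 18.2 times that of the surrounding sequence in the wild-type ChIP (bootstrap 95% interval 17.9 to 18.5). The same ratio was 2.96 in the extract (2.91 to 3.01) and 1.81 in the knockout ChIP (1.71 to 1.91).

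**Figure D2:**
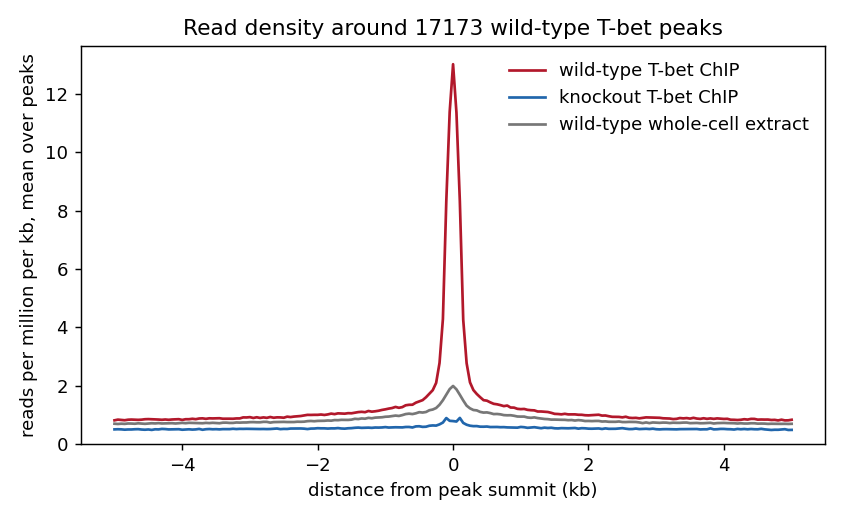
Mean read density (y axis, RPM per kb) against the distance from the summit in kb (x axis) over the 17173 wild-type peaks, for the 3 libraries. At the summit the density was 13.02 in the wild-type ChIP, 2.00 in the extract and 0.793 in the knockout ChIP.

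Most wild-type regions exceeded the knockout by more than regions away from peaks did. The knockout rule was passed by 16953 of 17173 peaks (98.7%, 95% interval 98.5 to 98.9). However, 1 kb windows away from all peaks, drawn for their extract level, already had a wild-type to knockout ratio of 2.29 (bootstrap 95% interval 2.25 to 2.34). This lay above the ratio of 2 that the rule asks for. Of 8262 such windows, drawn with replacement, 36.7% passed the rule (35.7 to 37.8). They had the mean extract level of 1 kb windows around autosomal peaks without a knockout peak or another peak within 10 kb. The peak windows had a ratio of 6.16 (6.07 to 6.24). With the ratio and its interval set against that of the windows away from peaks, a comparison chosen after the data were seen, 13342 peaks passed (77.7%, 95% interval 77.1 to 78.3). That number may be too high, since mean extract density over all peaks was 2.00 RPM per kb at the summit and 1.09 at 500 bp. Peaks are thus richer in extract reads than 1 kb windows around them. Away from peaks the knockout to extract ratio fell as the extract level rose. A ratio of at least 4 was reached, with the same condition on the interval, by 16044 peaks (93.4%). The 220 peaks that did not pass the knockout rule included 95 of the 96 shared with the knockout list, and 155 of them held fewer than 20 wild-type reads. With peaks divided into 4 equal groups by the caller's score, the share passing was 96.9% in the weakest group and 99.5% in the strongest. Set against the windows away from peaks, these shares were 55.5% (95% interval 54.0 to 57.0) and 98.0% (97.5 to 98.4). The median ratio over the knockout library was 7.27 and 12.7 in the same groups. The score comes from the same wild-type reads, so a rise from the weakest to the strongest group is partly built in. Median wild-type RPM was 2.05 and 6.24 in these groups, while the median knockout to extract ratio was 0.420 and 0.448. These comparisons describe 2 libraries, not 2 genotypes. In the windows away from peaks the ratio to the extract was 1.13 for the wild-type ChIP (bootstrap 95% interval 1.11 to 1.14) and 0.491 for the knockout ChIP (0.483 to 0.499). In the peak windows these ratios were 2.98 (2.95 to 3.01) and 0.484 (0.478 to 0.491). The gap between the sets of windows thus lay in the wild-type ChIP, whose excess over the extract the peak calling had selected.

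Among T-bet regions with at least 50 tags and no knockout peak, the 10 with the highest deposited fold enrichment were 417 to 847 bp long. They stood 16.7 to 79.1 times above the knockout. They were selected on wild-type reads and for having no knockout peak, so a high ratio over the knockout is partly built in. The intervals do not cover that selection. The highest deposited fold enrichment, 126.91, belonged to chromosome 10, 44541361 to 44541965, with 135 wild-type reads against 4 knockout and 8 extract reads (ratio over the knockout 37.4, 95% interval 14.3 to 139). A region on chromosome 7, 127323968 to 127324556, had an enrichment of 115.9 and held 118, 3 and 7 reads in the same order. On chromosome 15, 53323664 to 53324080 was enriched 110.13 and held 121, 8 and 3 reads. Chromosome 11 contributed 3 of the 10 named regions. They lay at 72304468 to 72305073 (enrichment 109.38), at 76924533 to 76925190 (109.32) and at 67376512 to 67377291 (97.02). The region on chromosome 4, 102383966 to 102384800, had an enrichment of 97.07. The most read-rich of the 10 was on chromosome 6, 67297718 to 67298492, with 272 wild-type reads against 12 knockout and 19 extract reads (ratio over the knockout 25.1, 95% interval 14.1 to 49.2). On chromosome 1, 94703101 to 94703783 held 143 wild-type and 2 knockout reads (ratio 79.1, 95% interval 21.5 to 660). On chromosome 7, 149564772 to 149565618 held 252 wild-type and 5 knockout reads (ratio 55.8, 95% interval 23.6 to 173). The lowest of the 10 ratios over the knockout had a 95% interval of 8.23 to 39.7.

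**Figure D3:**
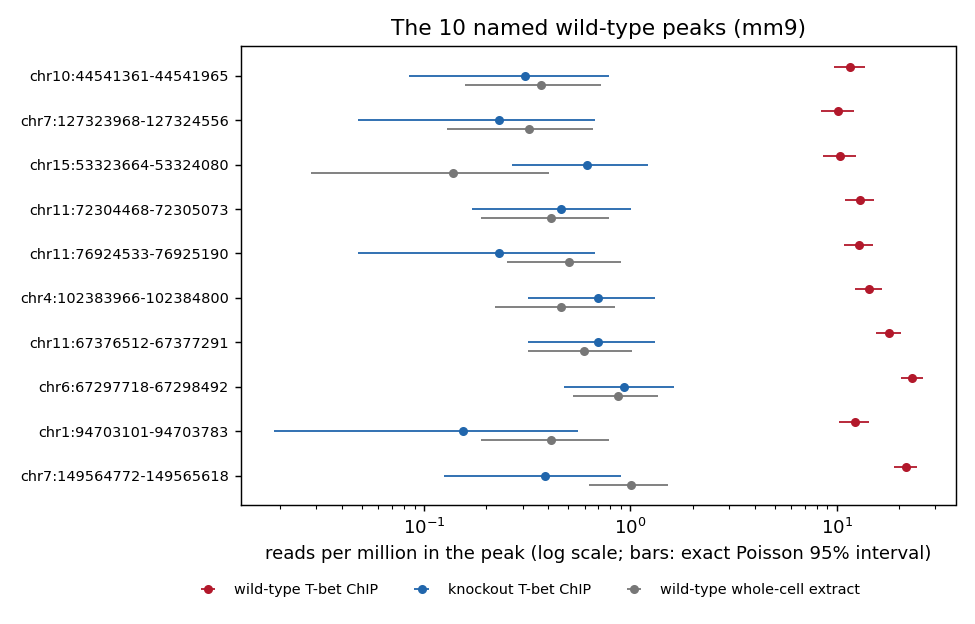
RPM (x axis, log scale) in the 10 wild-type peaks with the highest deposited fold enrichment (y axis, mm9 coordinates), with exact Poisson 95% intervals of the single library of each group. Wild-type ChIP values run from 10.1 to 23.2 and knockout ChIP values from 0.154 to 0.926.

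The 5 knockout peaks with the highest fold enrichment all lay on wild-type peaks and held more RPM in the knockout than in the wild-type ChIP. The first pair adjoined each other on chromosome 17, at 4626464 to 4626605 (enrichment 238.72) and 4626279 to 4626413 (202.85). The wild-type ChIP held 41 and 40 reads there, the knockout ChIP 110 and 79, and the extract 2 and 1. The others lay on chromosome 6 at 125568033 to 125568160 (enrichment 174.3) and 69466330 to 69466401 (156.14), and on chromosome 5 at 131995578 to 131995658 (129.06). Each of these others held 1 extract read, so its enrichment rests on very few extract reads. Their false discovery rates from the caller were 14.29%, 16.67% and 23.08% in the same order. The ratio of wild-type to knockout ChIP was between 0.413 and 0.658 at these 5, and its 95% interval reached above 1 at the chromosome 5 site and at the first of the chromosome 6 sites. The wild-type peak with the most tags, on chromosome 17 at 39979868 to 39985852, was chosen after its values were seen. It held 7953 wild-type, 6788 knockout and 6779 extract reads, and its ratio over the knockout was 1.297 (95% interval 1.255 to 1.340). With all reads as deposited it held 25247, 15780 and 14298 reads in the same order, so that ratio depends on the repeat reads.

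T-bet peaks lay in clusters, a comparison chosen after the data were seen. Joining peaks at most 12.5 kb apart gave 11167 regions, against a mean of 15313.5 when peaks were placed at positions of extract reads. A total of 296 regions held 5 or more peaks, against a mean of 7.32 and a maximum of 14 in 100 placements, and they contained 1893 peaks (11.0%). Another 7817 peaks (45.5%) stood alone. The size of the largest region, 16 peaks, lay within the range of the placements, whose largest region held a mean of 12.2 and a maximum of 25 peaks. The 5 regions with at least 14 peaks were chosen after their values were seen. The first, on chromosome 2 at 128192736 to 128259625, held 16 peaks, and the next, on chromosome 11 at 98960086 to 99016895, held 15. Summed over their peaks, wild-type reads exceeded knockout reads 7.10-fold (95% interval 5.94 to 8.54) and 9.62-fold (7.777 to 12.0045). The others held 14 peaks each. They lay on chromosome 3 at 37129980 to 37199215 (6.48-fold, 5.22 to 8.12), chromosome 5 at 134712655 to 134789864 (8.43-fold, 6.74 to 10.6) and chromosome 19 at 53470044 to 53518290 (14.3-fold, 11.7 to 17.7). None of these 5 regions held a knockout peak.

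The X chromosome carried few T-bet peaks, as the comparison of chromosomes, also chosen after the data were seen, showed. It held 270 peaks, or 1.65 per Mb (exact Poisson 95% interval 1.46 to 1.86). The autosomes ranged from 5.18 per Mb on chromosome 14 to 9.69 per Mb on chromosome 11, with a median of 6.91. Relative to extract reads, X held 287 peaks per 1000000 reads (254 to 324) and the lowest autosome, chromosome 18, held 620. Peaks on X held a median of 27 wild-type reads and those on autosomes 38, while the median deposited fold enrichment was 11.87 on X and 10.73 on autosomes. Read coverage of X was itself lower, at 0.668 of the median autosome density in the extract, 0.637 in the wild-type ChIP and 0.809 in the knockout ChIP.

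**Figure D4:**
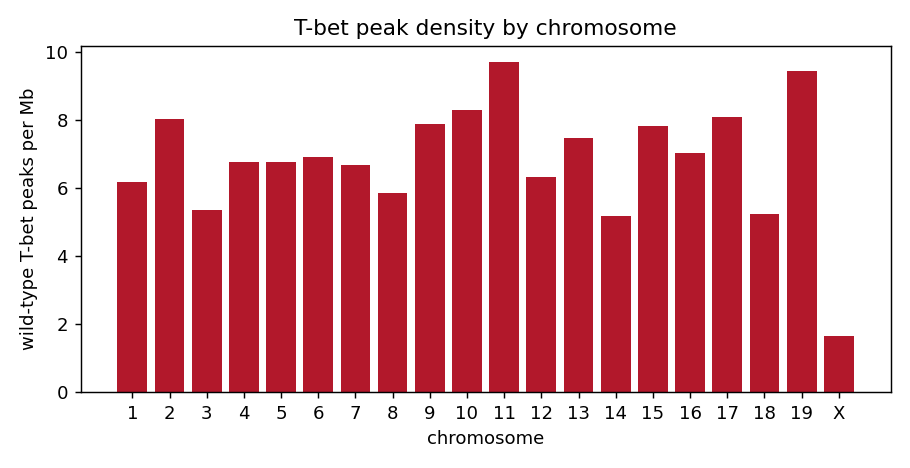
Wild-type T-bet peaks per Mb (y axis, bars from 0) for each chromosome (x axis), over the span covered by reads. The X chromosome, at 1.65 per Mb, lies below all 19 autosomes.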

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

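No paired analysis was possible because each group held 1 library, and for the same reason no library could be left out. The alternatives for peak location, gene lists, motifs and the Irf4 locus were not run, since no mm9 annotation or genome was used here. The direction of wild-type over knockout and over extract held under all alternatives run, both as the median over peaks and as the ratio of sums. Alternatives chosen after seeing the data were the false discovery limit of 5%, placement at extract reads, own surroundings, peaks without a knockout peak (with kept or all reads), thinning for the knockout rule, minimum knockout reads and the ratio of windows away from peaks as the level for the knockout rule. The wild-type list fell to 9515 peaks at a score of at least 100, 9755 at a fold enrichment of at least 10 and 11012 at a false discovery rate of at most 1%. The knockout list held 509 peaks at that score, 680 at that fold enrichment and 4 at a rate of at most 1% or 5%. The shared wild-type peaks numbered 20 with a reciprocal overlap of 50%, which a knockout peak of the median length, 79 bp, inside a wild-type peak of 552 bp does not meet, 49 at a score of at least 100 and 3 with knockout peaks at a rate of at most 5%. The cause of the shifts in the medians was not tested. The median wild-type to knockout ratio, 9.30, became 10.65 with all reads (10.74 without peaks shared with the knockout), 10.04 scaled to reads outside peaks and 10.63 at a score of at least 100. The median ratio over the extract, 4.03, became 4.25 with all reads (also 4.25 without shared peaks), 4.265 scaled to reads outside peaks, 4.095 at 5' ends and 4.691 at a score of at least 100. The median knockout to extract ratio, 0.420, became 0.4071 with all reads (also 0.4071 without shared peaks), 0.4115 scaled to reads outside peaks, 0.436 at 5' ends, 0.4348 after thinning and 0.4387 at a score of at least 100. The ratio of summed knockout to extract reads, 0.474, rose to 1.004 with all reads, crossing 1, and was 0.4088 once the 96 shared peaks were left out, so those peaks carry the change. The summed wild-type to knockout ratio likewise fell from 8.12 to 2.57 with all reads and was 10.1 without the shared peaks. Of the 9222 peaks with at least 5 knockout reads, 9011 passed the knockout rule; this smaller number follows from testing fewer peaks. Set against windows away from peaks, 13342 passed, since that rule asks for a higher ratio. With the extract as the control 16977 passed, which the peak calling over that extract fixed beforehand. Stretches without knockout reads numbered 91 instead of 33 with all reads, since repeat reads raise the counts in the other libraries. The median knockout count was 5 reads and 608 peaks held none; at these counts 70.1% of simulated changes by a fold of 4 passed the rule.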

Other observations

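The tests of scaling, of T-bet-bound regions against level-equalised windows, of the coverage of X, of the chromosome 12 stretch and of the correlations with gene density were chosen after the result was seen. Chromosomes with more genes carried more T-bet peaks. Over 20 chromosomes, wild-type peaks per Mb rose with protein-coding genes per Mb (Pearson's r = 0.65, 2-sided permutation p = 0.00149, adjusted 0.00149; Spearman's rho = 0.69, permutation p = 0.00092, adjusted 0.00092). Without chromosomes 7 and 11, the farthest in gene density, r was 0.71, and over the 19 autosomes it was 0.69 (permutation p = 0.00116). The share of all wild-type ChIP reads relative to the extract rose with gene density as well (r = 0.79, permutation p = 6e-05, adjusted 0.00018; rho = 0.83, permutation p = 2e-05, adjusted 3e-05; r = 0.76 without those chromosomes). The share of knockout ChIP reads fell (r = -0.70, permutation p = 0.00022, adjusted 0.00033; rho = -0.83, permutation p = 2e-05, adjusted 3e-05; r = -0.66 without those chromosomes). These are the 3 relations computed, and chromosomes are not independent replicates. Gene numbers came from GRCm38.p6.

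Wild-type peaks held a smaller share of reads in the knockout ChIP than in the wild-type extract, at a median RPM ratio of 0.420. Choice of the scaling factor is argued against, because the enrichment of the knockout library over its own surroundings was 0.610 of the extract's (bootstrap 95% interval 0.583 to 0.641). A candidate explanation that stays open is a loss of extract-rich DNA across the whole knockout library. In 1 kb autosomal windows away from all peaks, matched to 8331 peak windows on a random 50% of the extract reads, the knockout to extract ratio in the remaining extract reads was 0.5495 (0.541 to 0.558), against 1.02 over all such windows. A further loss at T-bet-bound regions stays open too, because the 95% intervals overlapped. Windows raised to the mean extract level of the peak windows had a ratio of 0.491 (0.483 to 0.499), and the peak windows 0.484 (0.478 to 0.491). At that extract level the ratio was thus nearly as low away from peaks as at them.

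Neither lower read coverage nor low gene density, each taken alone, accounted for the low number of T-bet peaks on the X chromosome. With each autosome thinned to the read density of X and its peaks tested again at the authors' p-value cutoff, using the expected tags implied by each peak's deposited tags and p-value, the lowest autosome, chromosome 18, kept 3.452 peaks per Mb (lower Poisson 95% limit 3.07), against 1.65 on X (upper limit 1.86). Low gene density would leave the number of peaks per gene unchanged, yet X had 0.2795 peaks per protein-coding gene (0.247 to 0.315) and the lowest autosome, chromosome 7, had 0.491. Inactivation of an X chromosome and the kinds of gene that X carries may contribute and were not tested. The labels do not give the sex of the mice, and read density on Y was 0.00790 of the median autosome in the extract, 0.0130 in the wild-type ChIP and 0.0256 in the knockout ChIP.

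A stretch of chromosome 12, 90893735 to 90915246, held 0 knockout reads but 72 wild-type ChIP and 157 extract reads, and it belonged to a chain of 7 such stretches between 90854733 and 90945519, with 23 knockout reads against 348 and 654. A chance gap is argued against, since 93.9 knockout reads were expected in the first stretch from the ratio over the chromosome. Loss of extract-rich DNA is argued against too, as extract density there was 0.888 of the chromosome mean. The 100 kb on either side kept knockout to extract ratios of 1.26 and 1.14 times that of the chromosome, which is consistent with DNA that may be missing from, or divergent in, the knockout mice. A deletion and a difference in sequence between mouse strains were not told apart, and the labels give no strain.

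Of the repeat reads set aside, 16.7% in the wild-type ChIP, 9.75% in the knockout ChIP and 49.2% in the extract fell in wild-type peaks. In the extract and the knockout ChIP, most of these lay in the 96 wild-type peaks shared with the knockout list. Repeat reads in all wild-type peaks numbered 395455 in the extract, 540433 in the knockout ChIP and 512291 in the wild-type ChIP. In the 17077 unshared peaks, reads as deposited numbered 400394, 134020 and 1084735 in the same order, against 384710, 96557 and 808569 kept reads. The extract and knockout shares thus do not describe the wild-type peaks in general. Away from peaks, windows with 25 to 60 reads in 50% of the extract had a knockout to extract ratio of 0.379 and a wild-type to extract ratio of 1.23, and windows with 1 to 2 such reads had 1.21 and 0.949.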
